A study of Mus musculus with 6 samples.

How the data were processed

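RNA was measured in the hippocampus of mice given ethynyluridine (EU), a uridine analogue that is built into new RNA and carries an alkyne for click chemistry, or phosphate-buffered saline (PBS) as the vehicle. Per the labels, EU was injected under the skin at 50 mg/kg once a day from postnatal day 3 to 5, tissue was taken on postnatal day 36, and RNA of both groups went through the same biotin click reaction and streptavidin pulldown. The PBS pulldown therefore measures background binding. Libraries were made with a total RNA kit, per the labels' protocols. There were 3 EU and 3 PBS libraries, assigned to groups by their titles.

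The deposited table holds raw read counts per gene for the 6 libraries, made by the authors with no normalization. Per the submitters' processing notes, bcl2fastq 2.20.0, STAR 2.7.10b and featureCounts 2.0.1 were used with the genome build GRCm39. The annotation release, the strand setting and the counted feature are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be assigned with certainty. The table has 55508 rows, of which 55416 are Ensembl genes with GRCm39 coordinates and a biotype. The other 92 rows are ERCC spike-in sequences, all at 0 counts in the 6 libraries, and were left out. Gene rows without a symbol (1492) took 0.0171% of the counts and were kept under their identifiers. The table held 0 columns of other samples.

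Totals lay between 39886723 and 58301239 counts per library. No library was a copy of another: the chi-square per degree of freedom between pairs of libraries, over genes with a summed count of at least 20, was 8.06 at its lowest. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these samples, which may be partly technical. Xist and Y-linked levels differed between replicates within each group, as between male and female tissue, so that spread is not only technical. Reads without molecular identifiers are not independent molecules, so intervals from counts cover counting error only.

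Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test on the counts, after filterByExpr and TMM scaling, two-sided, with treatment as the only term and Benjamini-Hochberg adjustment at 0.05. Standard errors are the absolute log2 fold divided by the square root of F. CPM values were scaled by the TMM factors, except where single libraries are compared by library totals. Gene lists (25) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, all in limma 3.58.1 and edgeR. Lists with at least 3 tested members were used. Shares of counts were compared by an exact two-sided permutation test, which for 3 against 3 libraries cannot give a p below 0.1. The planned Fisher's exact test of biotypes needed genes that passed the threshold as higher in EU, and there were 0, so it was not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

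The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule took the 10 largest changes and the 5 highest CPM in each direction among genes that passed, or, where none passed, the 10 genes with the smallest p in that direction. To these it added up to 3 members of each list with the smallest p, and always Malat1, Neat1, Meg3, Kcnq1ot1 and Xist. Other settings fixed beforehand were different scalings, no filter or a stricter one (CPM of at least 1 in at least 3 libraries and a total of at least 60), DESeq2 1.42.0, limma voom, robust estimation, the replicate number as a block, and leaving out each library. Added after seeing the data were voom with library quality weights, 5 brain region lists, set tests over biotypes, a Fisher's exact test and a split by level of biotypes at an unadjusted p under 0.05, and a correction for transcript GC content and length. That correction was a loess offset per library with a span of 0.5. It was run first as fitted and, after that form was seen to move the median of all genes, a second time with its median per library set to 0. Both forms are reported. GC content and length came from the longest GENCODE transcript of each gene, matched by identifier for 99.6% of tested genes. That annotation is of the earlier build GRCm38, so no coordinates were taken from it.

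The gene and list tests were tested on simulated data with 200 changed genes among 17914, drawn from the means and depths of these libraries. The test recovered 23 of 65 genes changed 1.5-fold, 40 of 67 changed 2-fold and 52 of 63 changed 4-fold, with 8 false calls. A list of 40 genes shifted 1.5-fold was called, and 0 of the 25 other lists. Genes were drawn independently of each other, and no library was made to deviate. The simulation therefore does not show how often the list test errs in these libraries. Nor does it show what share of changed genes the gene test would recover in them, where PBS replicate 2 deviates.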

Results

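RNA from the hippocampus of mice given EU or PBS as pups was taken on postnatal day 36, pulled down with streptavidin after a biotin click reaction and sequenced. The comparison asks which RNAs are retained from the days of labelling, with the PBS pulldown as background. The 3 EU libraries held 51279929, 39886723 and 41604852 counts and detected 26372, 25280 and 25849 genes. The 3 PBS libraries held 46863135, 43838026 and 58301239 counts and detected 23816, 19243 and 25306 genes. PBS replicate 2 stood apart, with a mean correlation of 0.938 with the other libraries, against 0.970 to 0.977 for the rest. Thinned to 39886723 counts, it detected 19185 genes, PBS replicates 1 and 3 detected 23649 and 24740, and the EU libraries 25280 to 25872.

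**Figure D1:**
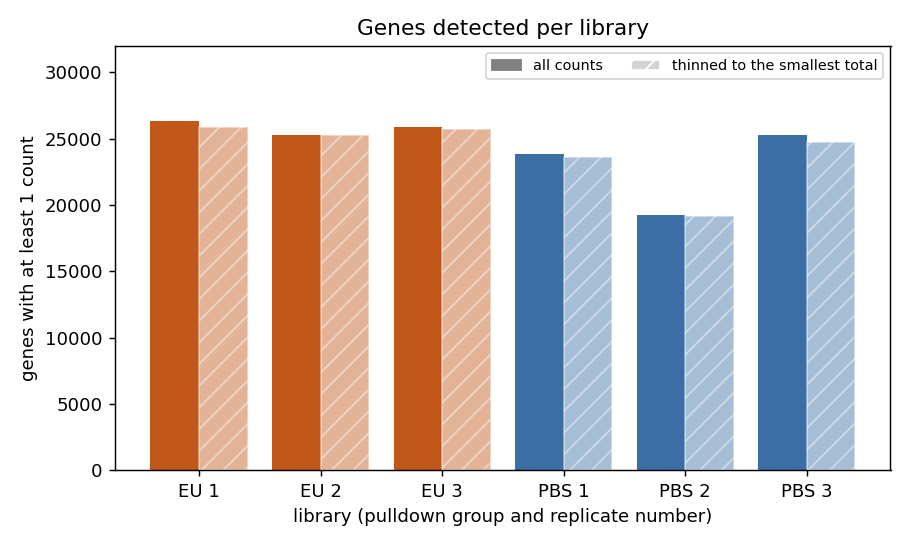
Number of genes with at least 1 count (vertical axis) in each EU and PBS library (horizontal axis), for all counts (solid bars) and after thinning to 39886723 counts (hatched bars). PBS replicate 2 lies at 19243 genes, below the 23816 to 26372 genes of the other 5 libraries.

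The abundant RNA classes were present in the pulldowns of both groups, and none of their shares passed the test. The 18S ribosomal RNA Rn18s took 10.94% ± 0.674 of counts in EU and 12.03% ± 0.855 in PBS (SD, n = 3 each; exact permutation p = 0.1, adjusted p = 0.2). Mitochondrial ribosomal RNA took 2.602% ± 0.139 in EU and 2.132% ± 0.0892 in PBS (SD, n = 3 each; exact permutation p = 0.1, adjusted p = 0.2). The 13 mitochondrial mRNAs took 3.283% ± 0.169 and 2.994% ± 0.214 (SD, n = 3 each; exact permutation p = 0.2, adjusted p = 0.2667). The 24 nuclear noncoding RNAs fixed as a list, among them Malat1 and Meg3, took 0.4423% ± 0.0602 in EU and 0.4113% ± 0.0126 in PBS (SD, n = 3 each; exact permutation p = 0.7, adjusted p = 0.7). Without EU replicate 3 that difference turned to -0.003732 percentage points, and without PBS replicate 3 the difference in mitochondrial mRNA was 0.1688 points in place of 0.2888. The 4 shares were adjusted together, and 0.1 is the smallest p the test allows.

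Gene by gene, no RNA separated the EU from the PBS pulldown at the adjusted threshold in edgeR with all 6 libraries, TMM scaling, the filter and treatment as the only term. The libraries were scaled to comparable totals, and the ERCC spike-in rows held no counts. A greater yield of all RNAs alike in the EU pulldown would therefore not show in these tests. Of 18511 genes tested with edgeR's quasi-likelihood test, 0 passed, and the smallest adjusted p was 0.0723. An unadjusted p under 0.05 was reached by 1459 genes, 710 higher and 749 lower in EU, against 926 expected by chance. CPM did not overlap between the groups for 2907 genes, or 15.7%, where chance gives 10%. DESeq2 called 288 genes (130 higher, 158 lower) and limma voom 12 (4 higher, 8 lower), and edgeR without a filter on low counts 248 (160 higher, 88 lower). Leaving out PBS replicate 2 gave 20 genes, 14 higher and 6 lower. With the replicate number as a block, edgeR called 18 genes, 11 higher and 7 lower.

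The nuclear RNAs Malat1, Neat1, Meg3, Kcnq1ot1 and Xist, which the rule always named, did not pass the test. Malat1, a speckle-associated noncoding RNA, stood at 2224 CPM ± 370 in EU and 2124 ± 143.8 in PBS (SD, n = 3 each), a log2 fold of 0.07 (SE 0.1, edgeR adjusted p = 0.895). That sign turned to -0.03 when libraries were scaled to mitochondrial mRNA, to -0.02 after the uncentred GC and length correction, and to -0.08 without EU replicate 3. Meg3, an imprinted noncoding RNA, had a log2 fold of 0.28 (SE 0.155, edgeR adjusted p = 0.728). In edgeR without the filter on low counts Meg3 passed (0.29, adjusted p = 0.03), at nearly the same fold. Its CPM overlapped between the groups (197.9 to 289.1 in EU and 161.5 to 226.9 in PBS), and its DESeq2 adjusted p was 0.729. Kcnq1ot1, which silences an imprinted cluster, had 0.21 (SE 0.157, edgeR adjusted p = 0.795). Meg3 had 0.08 without EU replicate 3 and 0.43 without PBS replicate 2, and Kcnq1ot1 had 0.007 without EU replicate 3 and 0.35 without PBS replicate 1. Neat1, the scaffold of paraspeckles, had 0.11 (SE 0.211, edgeR adjusted p = 0.923), with 0.38 without PBS replicate 2 and -0.11 without PBS replicate 3. Xist, the RNA of the inactive X chromosome, had 0.26 with an SE of 1.426, where EU replicate 1 and PBS replicate 1 held almost none. It turned to -0.02 without EU replicate 2, -0.32 without EU replicate 3 and -0.33 without PBS replicate 1, and had 0.84 without EU replicate 1, 0.70 with limma voom and 1.42 with library quality weights.

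Among genes with higher values in EU, the smallest p belonged to Rxfp1, the relaxin receptor, at 13.30 CPM ± 2.729 in EU and 4.648 ± 0.6874 in PBS (SD, n = 3 each). Its log2 fold was 1.51 (SE 0.190, edgeR adjusted p = 0.0723). Rxfp1 (ENSMUSG00000034009) lies on the minus strand of chromosome 3 at 79548918 to 79645187 in GRCm39. The zinc finger gene Tshz3 (log2 fold 0.91) and the calcium pump Atp2b4 (0.63) had the same adjusted p. The transcription factor Mef2c stood at 245.0 CPM against 131.7 (log2 fold 0.90, edgeR adjusted p = 0.0956). Tmem44, Necab1, Cbln4 and the mitochondrial ribosomal RNA mt-Rnr2 had log2 folds of 0.75, 0.67, 0.90 and 0.38 at that adjusted p. Bmp3 (1.08) and Lgi2 (0.62) complete the 10 genes. After the GC and length correction mt-Rnr2 had 0.08 in the uncentred and 0.21 in the centred form.

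Among genes with lower values in EU, Hpca, the calcium sensor hippocalcin, stood at 781.1 CPM ± 29.54 in EU and 978.9 ± 14.44 in PBS (SD, n = 3 each), a log2 fold of -0.33 (SE 0.044, edgeR adjusted p = 0.0723). The kinase gene Ptk2b (-0.34), Plppr2 (-0.42) and the pentraxin receptor Nptxr (-0.36) had the same adjusted p. Rny3, a small Y RNA, stood at 29.04 CPM ± 1.751 against 63.36 ± 15.73 (SD, n = 3 each), a log2 fold of -1.12 (SE 0.152, edgeR adjusted p = 0.0723). Rny3 (ENSMUSG00000064945) lies on the plus strand of chromosome 6 at 47758558 to 47758659 in GRCm39. Its reads can be shared with near-identical copies. Plxna1, Wasf1, Cdk14, Cnih2 and the CA1 gene Fibcd1 had log2 folds of -0.40, -0.31, -0.32, -0.31 and -0.52 with edgeR adjusted p from 0.0836 to 0.1058. DESeq2 called 20 of the 20 genes, which is not independent evidence, since they were picked for a small p in the same libraries.

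**Figure D2:**
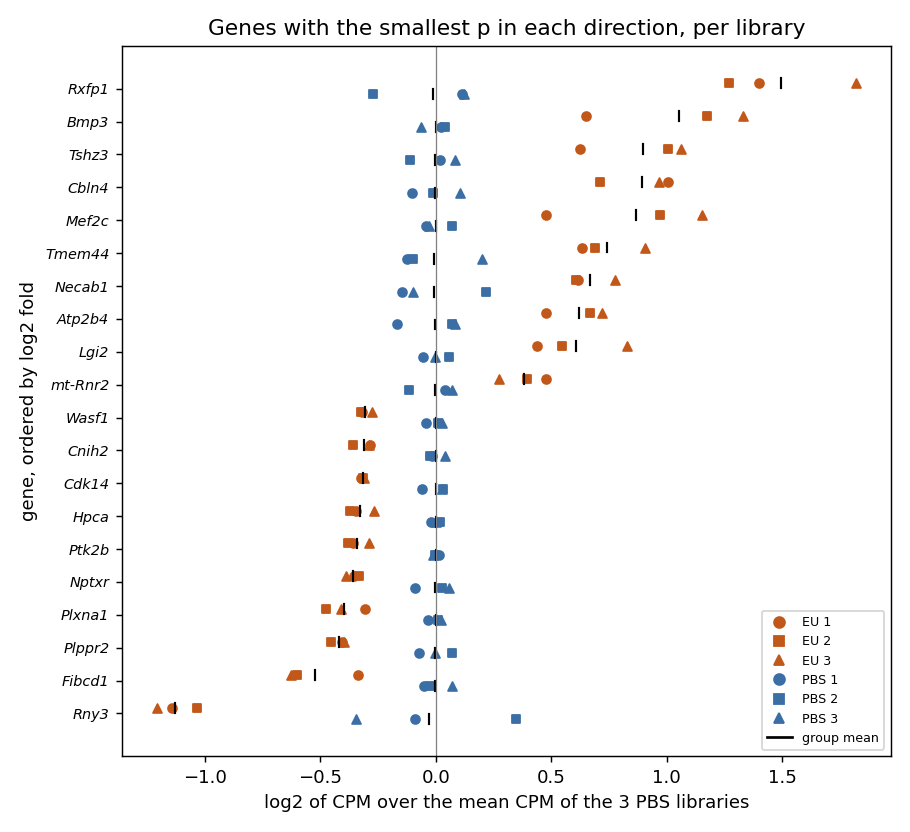
The log2 of CPM over the mean CPM of the 3 PBS libraries (horizontal axis) for the 10 genes with the smallest p in each direction (vertical axis), with 1 point per library and black bars at group means. EU points lie on 1 side of all PBS points for each gene, from Rxfp1 at a log2 fold of 1.51 to Rny3 at -1.12, and none passed the adjusted threshold in edgeR.

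By camera with a preset correlation, markers of the principal neurons of the hippocampus were lower in EU as groups, and with an estimated correlation neither list passed. Of 18 dentate granule neuron genes, 15 had lower values in EU, with a median log2 fold of -0.16 (camera adjusted p = 0.00031, and adjusted p = 0.8506 with an estimated correlation). Examples were C1ql2 at 51.52 against 65.98 CPM, Plk5 at 7.039 against 10.12 and Jun at 106.5 against 122.1. Of 18 pyramidal neuron genes, 12 had lower values, with a median of -0.20 (camera adjusted p = 0.0045, and adjusted p = 0.8506 with an estimated correlation). Fibcd1, Nptx1 (log2 fold -0.33) and Homer3 (-0.44) had lower values, while Meis2 (0.47), which neurons outside the hippocampus also express, had a higher one. No member passed over all genes. Adjusted over the list alone, 1 dentate gene was lower, and 7 pyramidal genes were lower and 3 higher. Levels per library (mean log2 CPM relative to the 6 libraries) overlapped between the groups for both lists. The dentate level was -0.044 in EU replicate 3 and -0.061 in PBS replicate 2. The pyramidal level was 0.053 in EU replicate 3 and -0.039 in PBS replicate 1. Without PBS replicate 1, whose dentate level was the highest of the 6, the dentate call ended (camera adjusted p = 0.248). In the same libraries 24 neocortex genes, a list written after the gene results were seen, had a median log2 fold of 0.29 (camera adjusted p = 0.0003478, and adjusted p = 0.1544 with an estimated correlation).

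By the same preset test, and not with an estimated correlation, splicing factor mRNAs were higher and presynaptic mRNAs lower in EU as groups. Of 39 splicing and nuclear speckle genes, 28 had higher values, with a median log2 fold of 0.07 (camera adjusted p = 0.0202, and adjusted p = 0.8506 with an estimated correlation). Hnrnpa2b1, Luc7l3 and Pnisr had log2 folds of 0.25, 0.36 and 0.32, and 3 members were higher adjusted over the list alone. Of 25 presynaptic genes, 17 had lower values, with a median of -0.07 (camera adjusted p = 0.0202, and adjusted p = 0.861 with an estimated correlation). The synapsin Syn2, the glutamate transporter Slc17a7 and the complexin Cplx2 had -0.31, -0.21 and -0.17, and 5 members were lower adjusted over the list alone. The splicing call ended without EU replicate 1 (adjusted p = 0.1598), without PBS replicate 1 (0.248) and after the uncentred GC and length correction (0.6485). The presynaptic call ended without EU replicate 1 (0.1259), PBS replicate 2 (0.1402) or PBS replicate 3 (0.3072), with library totals only (0.0523) and after the centred correction (0.1772). Levels per library (mean log2 CPM relative to the 6 libraries) overlapped between the groups for both lists. The splicing level was -0.028 in EU replicate 2 and -0.012 in PBS replicate 3. The lowest presynaptic level, -0.06, was that of PBS replicate 1.

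**Figure D3:**
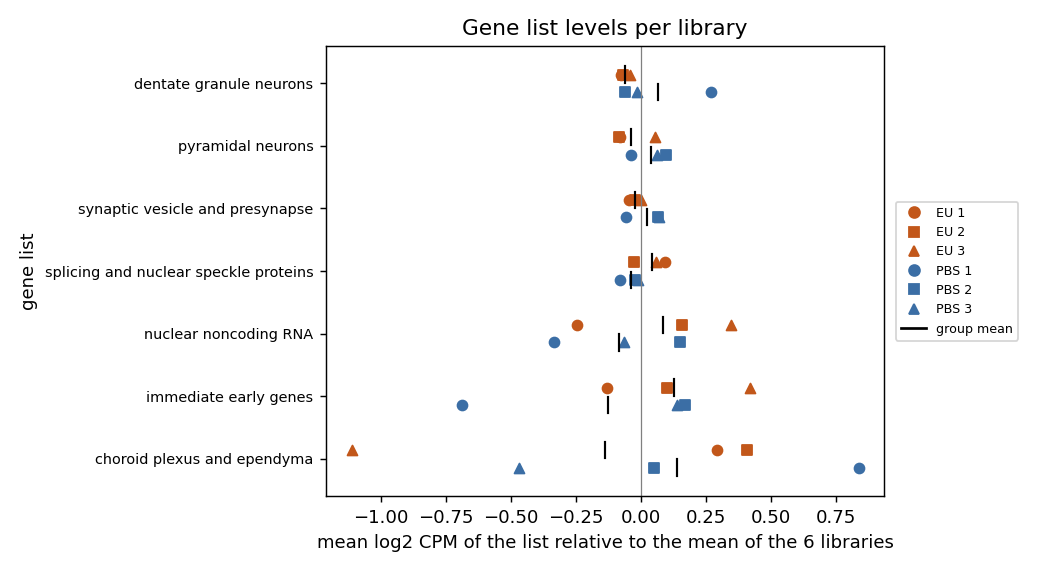
Mean log2 CPM of each list relative to the mean of the 6 libraries (horizontal axis) for 7 gene lists (vertical axis), with 1 point per library and black bars at group means. Dentate granule genes stand at 0.269 in PBS replicate 1 and between -0.077 and -0.017 in the other 5 libraries, and choroid plexus genes range from -1.114 to 0.836.

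Lists of nuclear noncoding RNAs and snoRNAs, and of mRNAs of chromatin regulators, very long genes and histones, did not pass with all 6 libraries, TMM scaling, treatment as the only term and no correction for GC and length. Of the 24 nuclear noncoding RNAs, 20 had higher values in EU, with a median log2 fold of 0.10 (camera adjusted p = 0.0521, and adjusted p = 0.861 with an estimated correlation). That list passed camera without PBS replicate 2 (median 0.20, adjusted p = 0.0004921), EU replicate 1 (0.005587) or EU replicate 2 (0.00776), with library totals only (0.03849) and after the centred correction (0.02639). Snhg14, Rian and Mirg, from imprinted clusters, had log2 folds of 0.25, 0.18 and 0.73. Chromatin regulators had a median of 0.03 (adjusted p = 0.2755) and very long neuronal genes 0.02 (0.4639). Replication-dependent histones had a median of 0.03 while their camera direction was down (0.8602). The 17 tested snoRNAs had a median of -0.21 (0.0933), with Snora73b at 32.19 CPM in EU and 48.66 in PBS. Adjusted over the list alone, 1 very long gene, Dpp10 at a log2 fold of 0.55, was higher. The snoRNA list passed without EU replicate 3 (0.03135) or PBS replicate 3 (0.005529), and the chromatin list without EU replicate 2 (0.04464) and after the centred correction (0.0002412). Without EU replicate 3 the camera direction turned to down for the chromatin (0.8229) and very long gene lists (0.5178), as it did for the latter without PBS replicate 1 (0.6216).

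Other neuronal and metabolic lists did not pass under those settings either. Postsynaptic and dendritic mRNAs had a median log2 fold of -0.06 (camera adjusted p = 0.0521), with Gria1 at -0.16, Camk2a at -0.14 and Kif5a at 0.21. Immediate early genes had a median of 0.22 (0.1033), and Fos ranged from 5.377 to 25.32 CPM within PBS and from 19.44 to 43.82 within EU. That list passed without EU replicate 1 (0.0004005), EU replicate 2 (0.04464), PBS replicate 2 (median 0.36, 0.001083) or PBS replicate 3 (0.03758), while its camera direction was down without PBS replicate 1 (0.248). With an estimated correlation its camera adjusted p was 0.861 with all libraries and 0.7072 without PBS replicate 2. Mitochondrial mRNAs had a median of 0.08 (0.2492), nuclear-encoded respiratory chain genes -0.02 (0.1643) and cytosolic ribosomal protein genes 0.07 (0.0708). The mitochondrial list includes mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l, whose group means were at most 6.781 CPM. Adjusted over the list alone, 2 mitochondrial mRNAs were higher, mt-Nd6 at 183.8 against 97.22 CPM and mt-Co1 at 10420 against 9378. Reads of mt-Nd6 cannot be told from those of its antisense neighbours, since the strand setting is not given. GABAergic interneuron genes had a median of 0.04 (0.7811), with Reln at 0.26 higher adjusted over the list alone. Without EU replicate 3 the postsynaptic (6.436e-06), mitochondrial mRNA (0.03072) and ribosomal protein lists (0.002297) passed, without PBS replicate 1 the postsynaptic list (0.007812), and without EU replicate 1 the respiratory chain list (0.02442). The respiratory chain list also passed after the uncentred (6.139e-05) and centred (0.001632) corrections, and the ribosomal protein list with library totals only (0.02451). The camera direction turned to down after the uncentred and the centred correction for mitochondrial mRNAs (0.3032 and 0.1544) and ribosomal proteins (0.0853 and 0.8843), and to up after the centred one for postsynaptic mRNAs (0.8843).

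Lists of glia, vessels, immature and dividing cells and neighbouring tissue gave no call under those settings. Astrocyte genes had a median log2 fold of 0.02 (camera adjusted p = 0.4639), mature oligodendrocyte genes -0.04 (0.4222) and microglial genes 0.02 (0.4108). Endothelial and mural genes had -0.01 (0.4108), meningeal and fibroblast genes 0.06 (0.9117) and the 5 tested blood genes 0.18 (0.1033). Oligodendrocyte precursor genes had a median of -0.002 and a mean of 0.021 with a camera direction of down (0.9908). Proliferating cell genes had a median of -0.04 and a mean of 0.045 with a direction of up (0.9284). Progenitor and neuroblast genes had -0.10 (0.1033), and adjusted over the list alone Stmn1 was higher (0.38) and Hes5 lower (-0.82). Choroid plexus and ependymal genes had -0.26 (0.0708), and their leading gene Ttr ranged from 682.1 to 4932 CPM over the libraries. That list passed without EU replicate 1 (0.005386), EU replicate 2 (0.0003139) or PBS replicate 3 (0.0009428), with library totals only (0.03849) and after the centred correction (0.04116), while its camera direction was up without EU replicate 3 (0.5178) or PBS replicate 1 (0.8608). The oligodendrocyte list passed after the uncentred correction (0.008141). The camera direction of the interneuron, astrocyte, microglial, meningeal, precursor and proliferating cell lists, which passed in none of these settings, turned in at least 1 of them.

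All list results carry a limit. Of the 25 lists, camera with the preset correlation called 4, while with an estimated correlation or with fry 0 were called, and the 9 other splits of the 6 libraries into 3 and 3 gave 5 to 9 called lists. With the replicate number as a block the preset test called 8. It added nuclear noncoding RNAs (camera adjusted p = 0.01271), postsynaptic mRNAs (0.03338), immediate early genes (0.0001957) and choroid plexus genes (0.001509).

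Of 1673 long noncoding RNAs tested, 910 had higher values in EU, with a median log2 fold of 0.07, as had 7701 of 14791 protein-coding genes (median 0.009). Among the long noncoding RNAs 0 passed in edgeR with the filter on low counts or were higher in DESeq2. Without the filter Meg3 passed as higher in EU (log2 fold 0.29, edgeR adjusted p = 0.03), although its CPM overlapped between the groups. At an unadjusted p under 0.05, chosen after no gene passed, 29 long noncoding genes were higher and 20 lower, against 655 and 672 protein-coding genes. The Fisher odds ratio of the long noncoding share at that p was under 1 in both directions, 0.381 for genes higher and 0.254 for genes lower in EU, so it gave no direction. Split by mean log2 CPM into 4 equal groups of all tested genes, also after the results were seen, 70.4% of the long noncoding and 12.6% of the protein-coding genes lay in the lowest group, where 1.02% and 2.14% reached that p. In the group above it the shares were 6.37% and 5.13%, and in the next 9.26% and 8.59%. In the highest group they were 29.4% of 17 long noncoding and 15.3% of 4595 protein-coding genes. Of those 17, 15 had higher values, and at that p 5 were higher and 0 lower. Among the protein-coding genes there, 262 were higher and 442 lower at that p. Median log2 folds of long noncoding and protein-coding genes were 0.124 and 0.21 in the lowest group and -0.032 and 0.033 in the group above it. They were 0.048 and 0.013 in the next and 0.121 and -0.013 in the highest group. The higher median of long noncoding genes as a whole was therefore not seen at like levels in the groups that held most of them. Without PBS replicate 2, 86 long noncoding genes were higher and 31 lower at that p, against 783 and 798 protein-coding genes, and the shares in the lowest group were 5.6% and 5.88%. Genes are not independent replicates.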

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

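Tests with library quality weights and with a GC and length correction were chosen after the data were seen, the centred form of that correction after its uncentred form had moved the median of all genes. The count of differing genes was 0 in edgeR with library totals only, RLE or upper quartile scaling, the stricter filter, robust estimation and both forms of the correction. Scaling to mitochondrial mRNA gave 1 gene (0 higher, 1 lower) and shifted the median log2 fold of all genes by -0.113. The uncentred correction shifted it by -0.109 and the centred one by 0.006. Testing without a filter gave 248 genes (160 higher, 88 lower), DESeq2 288 (130 higher, 158 lower, with 6819 genes given no adjusted p), limma voom 12 (4 higher, 8 lower) and voom with quality weights 48 (19 higher, 29 lower), where PBS replicate 2 had a weight of 0.217. DESeq2 and voom shared 12 genes. Leaving out each library gave 0 to 20 genes, 0 to 14 higher and 0 to 6 lower, the highest without PBS replicate 2, of which DESeq2 also called 17. The cause of these differences was not tested.

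The replicate numbers did not meet the bound for pairing: deviations of same-numbered libraries correlated at 0.064, 0.024 and 0.098, not over 0.1. Each library nevertheless correlated best with its own number, and Xist and Y-linked levels followed the number in both arms, so pairing stays open. With the replicate block 18 genes were called (11 higher, 7 lower) and 8 lists, against 0 and 4 without it, the 4 others being nuclear noncoding RNAs (camera adjusted p = 0.01271), postsynaptic mRNAs (0.03338), immediate early genes (0.0001957) and choroid plexus genes (0.001509). The count of lists was 0 with an estimated correlation and 0 with fry, 5 after the uncentred and 7 after the centred correction, and 3 to 8 with each library left out. The 20 genes with the smallest p kept their sign in 380 of 380 refits, of which 87 passed the threshold, and mt-Rnr2 went from 0.384 to 0.078 after the uncentred and 0.207 after the centred correction. Malat1 turned to -0.033 with mitochondrial scaling and to -0.021 after the uncentred correction, but not after the centred one (0.092). With each library left out Malat1 ranged from -0.084 to 0.148, Neat1 from -0.11 to 0.377 and Xist from -0.332 to 0.838. Without EU replicate 2 and EU replicate 3 Xist had -0.017 and -0.322, and with quality weights 1.423. The difference in the nuclear noncoding share ranged from -0.003732 to 0.05009 percentage points. The cause was not tested. The difference in the mitochondrial share ranged from 0.1688 without PBS replicate 3 to 0.3857 without EU replicate 3. Long noncoding genes were 0 of the 130 genes called higher by DESeq2, the 11 with the block, the 14 without PBS replicate 2 and the 1 without EU replicate 1, and the other settings tried for them called no gene higher. Testing without a filter was not among those settings, and there Meg3 was called higher (log2 fold 0.291, edgeR adjusted p = 0.03), with CPM that overlapped between the groups. That fit called 20 of the 20 genes with the smallest p. Low counts limit calls on long noncoding genes, with a median mean count of 30.7 against 814 for protein-coding genes, and without PBS replicate 2 more of them reached an unadjusted p under 0.05 (86 higher, 31 lower).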

Other observations

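The brain region lists, the set tests over biotypes, the grouping of mitochondrial genes by strand, the tests of the neocortex list, of depth and of X-linked copies, the counts of genes over splits and the genes named from these groups were chosen after the results were seen. By camera with a preset correlation 4 of 18 biotypes, of small structured RNAs and mitochondrial tRNAs, stood apart, and with an estimated correlation none did. All 9 tested mitochondrial tRNA genes had higher values in EU, with a median log2 fold of 0.995 (camera adjusted p = 7.387e-07 over 18 biotypes, adjusted p = 0.0913 with an estimated correlation, fry adjusted p = 0.0164), and 1.195 without PBS replicate 2 (0.2149 with an estimated correlation, fry 0.09218). mt-Tp stood at 6.533 CPM ± 0.4138 in EU and 2.938 ± 0.6408 in PBS (SD, n = 3 each), and most other tRNAs lay near or under 2 CPM. The 4 light-strand tRNAs had a median of 1.15 and the light-strand mRNA mt-Nd6 had 0.92, against 0.58 for the 5 heavy-strand tRNAs and 0.06 for the 12 heavy-strand mRNAs. That difference between strands was not tested, and the strand setting of the counting is not given. Of the 12 heavy-strand mRNAs, mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l had group means from 0.718 to 6.781 CPM. Of these only mt-Atp8 had a higher value in EU. The others had group means from 2869 to 10420 CPM and log2 folds from 0.038 to 0.152. The median mixes both sets, and the cause of the low counts was not tested. Of 20 misc_RNA genes, which hold Y RNAs and 7SK copies, 15 had lower values, with a median of -0.48 (camera adjusted p = 1.739e-07, adjusted p = 0.4415 with an estimated correlation), and -0.30 without PBS replicate 2 (camera adjusted p = 1.389e-05, 0.5597 with an estimated correlation). The most abundant 7SK gene went the other way, at 7575 CPM in EU and 6511 in PBS (log2 fold 0.22). Rny1 stood at 35.84 CPM in EU and 52.89 in PBS, and Vault at 4.185 and 7.151. Of 42 snoRNA genes 28 had lower values (median -0.53, camera adjusted p = 0.0003242, 0.476 with an estimated correlation), and of 29 snRNA genes 21 (median -0.51, camera adjusted p = 0.0476, 0.476 with an estimated correlation). Without PBS replicate 2 the snoRNA median was -0.27 (camera adjusted p = 0.02831, 0.6565 with an estimated correlation), and the snRNA median was -0.13 and its call ended (0.451). Many of these have near-identical copies, so their counts are uncertain.

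Genes of other brain regions were also looked at, and those named here were chosen after their values were seen. The cerebellar granule cell genes Gabra6 and Cbln3 were near the floor in EU, with Cbln3 at 0.5516 to 0.697 CPM, and higher in each PBS library, with Cbln3 at 1.779 to 3.19 and Gabra6 at 0.8233 to 1.802. With all 6 libraries neither passed (edgeR adjusted p = 0.1352 for Cbln3 and 0.1832 for Gabra6). Without PBS replicate 2 Cbln3 passed (log2 fold -2.397, edgeR adjusted p = 0.01764). The striatum list had a camera p of 0.2003, the thalamus and midbrain list 0.0423 (adjusted p = 0.0705) and the cerebellar granule list 0.6108, the last with a median of 0.01 and a mean of -0.03. Of the list members Nr4a2, Otx2, Tac2, Eomes and Kcnh7 also stand in the lists fixed earlier, and the hippocampus expresses many of the neocortex genes, with Tbr1 at 96.94 CPM in EU and 73.04 in PBS.

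Hippocampal field genes had lower and neocortical genes higher values in EU: 19 of 21 field genes were lower (median log2 fold -0.21, camera adjusted p = 1.406e-09, adjusted p = 0.0347 with an estimated correlation) and 15 of 24 neocortex genes higher (median 0.29). The field list was also written after the gene results were seen. Splits that mixed the groups gave it a preset camera p as low as 2.777e-05, so that p is not evidence on its own. Transcript GC content or length, and PBS replicate 2 alone, are argued against as the whole cause for the field genes, by the size of their median and not by that p. Their list had a median of -0.35 (camera p of 7.826e-10) after the uncentred correction, which shifted all genes by -0.109. It had -0.23 (1.054e-08) after the centred correction and -0.22 (5.873e-10) without PBS replicate 2. The SD over genes was 0.189 before and 0.205, 0.2 and 0.21 in these fits. With an estimated correlation the adjusted p was 0.05285, 0.0724 and 0.1352 in these 3 fits, so that call, close to the threshold before, ended although the median was not smaller, with 1 library fewer in the last fit. The neocortex median fell to 0.181 after the uncentred correction, with 13 of 24 genes higher. It was 0.315 after the centred one and 0.3 without PBS replicate 2. Different amounts of neighbouring tissue at dissection may account for the pattern. The neocortex list had a camera p of 0.0001391 in a test chosen after the results were seen. That list is itself part of the pattern, so its test cannot tell this cause from others. Its camera p was 0.0617 with an estimated correlation, and 1 split that mixed the groups gave 1.357e-05. Retention of EU-labelled RNA stays open and was not tested, since treatment and dissection cannot be separated with these libraries.

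PBS replicate 2 detected the fewest genes. Lower depth is argued against, since it detected 19185 genes when thinned to the smallest total, against at least 23649 in the others, and so is GC content or length, which explained 1.28% of the variance of its log2 deviation. Of genes with an expected count of 10 to 30, 39.9% had 0 counts in PBS replicate 2 (95% exact binomial interval 38.2 to 41.7). A library built from fewer distinct molecules would give such a share. The shares were 4.1% and 5.02% in PBS replicates 3 and 1, and 0.85% to 1.28% in the EU libraries. Thinned to the smallest total, each PBS library also detected fewer genes than each EU library, 19185 to 24740 against 25280 to 25872. The cause of that difference between the groups was not tested. No biological explanation was tested.

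Xist stood at 0.7605 CPM in EU replicate 1 and 0.08535 in PBS replicate 1, and between 144.3 and 203.3 in the other 4 libraries. Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) summed to 97.72 and 80.58 CPM in the libraries numbered 1, and the Xist-positive libraries numbered 2 still held 10.3% (EU) and 10.7% (PBS) of that. Reads of X-linked copies are argued against, since the sum in number 2 was at least 4.3 times that in number 3 in both arms. A part of male material or reads may be present, and the libraries cannot tell. The highest over the lowest share among the 4 genes was 1.44 in the EU arm, as such material would give, and 5.11 in the PBS arm. In PBS replicate 2 Eif2s3y rested on 12 counts, but Uty (17.9% of its level in number 1, on 136 counts) and Kdm5d (8.05%, on 62) also differed. No biological explanation was tested.

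The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The count of 0 genes that differed, higher or lower, is matched by any split (10 of the 10, with a highest other value of 0), so the splits say nothing about it. For genes at an unadjusted p under 0.05, 1 of the 10 splits was as large as the real 1459, with a highest other of 903. For gene lists, 10 of the 10 splits gave at least the real 4, with a highest other of 9, so the preset correlation calls lists in groupings that ignore the treatment. For the size of the median log2 fold, 1 of the 10 splits was as large for each of 4 groups chosen after their values were seen. The real value and the highest other were 0.286 and 0.226 for the neocortex list and 0.214 and 0.144 for the hippocampal field list. They were 0.995 and 0.513 for mitochondrial tRNA genes and 0.484 and 0.421 for misc_RNA genes.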
